A study of Mus musculus with 6 samples.

How the data were processed

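RNA was sequenced from 6 cultures of MLE12, an immortalized mouse lung epithelial cell line, with libraries from a messenger RNA preparation kit. Monolayers were wounded with a pipet tip or left intact. The labels define 6 groups with 1 library each. They were the parental line without a scratch, the parental line 24 hours after a scratch, and 4 knockout lines (Lingo1, Lingo2, Lingo3 and TROY) 24 hours after a scratch. No group had a second library, so there was no replicate error against which a difference could be held, and no p-value was computed. How the knockouts were made, whether each line came from 1 cell, when the libraries were made and whether they kept the strand of the RNA were not given in the sources used here.

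The authors deposited a table of raw read counts per Ensembl gene, with the summary lines of HTSeq at its end. The labels name Trimmomatic 0.39, STAR, HTSeq and edgeR and the mouse genome build GRCm38, without their order or settings, and the versions of the other tools are not given in the sources used here. A second table deposited by the authors held RPKM values for the same 6 libraries, which in the 7624 well-counted genes checked followed the counts times a factor per gene and a factor per library, to within an SD of 0.00125 log2 units. The same deposited table held log2 ratios of those RPKM values for the 5 comparisons analysed here, with no p-value. It listed 13559 genes after a filter on low values that is not stated. The authors' log2 ratios were used only as a check on the ratios computed here.

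Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 over all 6 libraries and are given as CPM (counts per 1000000 scaled reads). Of the 46078 gene identifiers in the count table, 45229 were matched by identifier to GENCODE release M21, on build GRCm38, for symbols, gene types and positions. The 12078 genes with a mean of at least 1 CPM over the 6 libraries were tested. For each comparison of 2 libraries the fold is the ratio of scaled counts. Its 95% interval was taken from the exact Clopper-Pearson interval of the share of the 2 counts that fell in the first library. These intervals, the Poisson intervals of single levels and the limits below cover counting error only, because reads without molecular identifiers are not independent molecules and because no variation between cultures was measured. A gene passed the size rule when its fold was at least 2 in either direction and the bound of its interval nearest to 1 was beyond 1.5-fold. Where 1 library had 0 counts, the fold was computed against a floor of 3 counts in that library and is written as at least that fold. With 1 to 3 counts, the ratio is given with its interval. The words higher and lower, used of a gene without further values, mean that the gene passed this rule.

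The 5 comparisons were the scratched against the unscratched parental library, and each mutant library against the scratched parental library. Because the 4 mutant comparisons share 1 parental library, their overlap was set beside 20 simulations of mutant lines without any effect. The simulations drew counts at the mean scaled level of each gene over the 5 scratched libraries, mutants included. They used Poisson error alone and added gamma-distributed noise (coefficient of variation 0.2). A coefficient of 0.1 was added after that of 0.2 was seen to scatter far more than the parental pair did. Each scratched library was also compared, by the same size rule, with each of the other 4 scratched libraries. A library stood apart for a gene when it passed the size rule in the same direction against all 4.

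For 36 lists of genes (pathways, cell type markers and gene families, 676 members in all), the median log2 fold of the measured members was compared with 10000 random lists of the same size, drawn from 25 bins of mean expression, and is given with its percentile. The percentile describes these 2 libraries and is not a test, since genes of a pathway move together between cultures. In 100 random lists per comparison on simulated data, between 2 and 11 fell outside the central 95%. The shift of each chromosome was measured in the same way. On simulated data with known folds, the size rule recovered between 94% and 100% of genes changed 3-fold, and between 96% and 100% of those changed 4-fold or 8-fold. With counting error alone, as in these simulated data, it called between 0 and 2 unchanged genes per comparison.

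Named genes were chosen by a rule. They are the 4 targeted genes, the 10 genes in each direction with the largest fold at the interval bound nearest to 1 in each comparison, up to 4 members of each list past the size rule, up to 10 genes in each direction past the rule in all 4 mutants, and up to 6 in each direction for which 1 library stood apart. Predicted genes with Gm or Rik symbols, pseudogenes and clone names were left out of the rankings, and the text says where another gene is named, apart from further members of the fixed lists, which are named as examples without this rule. The groups, comparisons, gene lists, size rule, rule for named genes and first set of alternatives were chosen before the data were examined.

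The alternatives tried were DESeq2 1.42.0 size factors, total counts as the only scaling, no filter or a mean of at least 5 CPM, a fold of at least 1.5 or 4, no condition on the interval, and the mean in place of the median of a list. Added after seeing the data were the unscratched parental library as control, both parental libraries as control, protein-coding genes only (for the counts and for the random lists), the counts without genes that stood out in the scratched parental library, and a log2 fold of 0 for genes raised by the scratch that had too few counts for a fold. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not realigned. Because strandedness is not given in the sources used here, reads of a gene and of a gene that overlaps it on the other strand cannot be separated, and reads that aligned to more than 1 place were not counted, so near-identical copies such as pseudogenes and members of gene clusters are less certain.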

Results

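Messenger RNA was measured in 6 libraries of MLE12 cells, 1 per group, with between 28109825 and 30776294 reads counted in genes. The unscratched parental library had 28224654 and the scratched parental library 29307338. The Lingo1, Lingo2, Lingo3 and TROY mutant libraries had 28109825, 28579338, 30776294 and 30597910. Between 19206 and 20307 genes had at least 1 count. The floor of 3 counts per library stands at between 0.0984 and 0.108 CPM, where CPM stands for counts per 1000000 scaled reads. A count of 0 has a 95% Poisson upper limit of between 0.121 and 0.133 CPM. The no-feature share is the part of the uniquely aligned reads that HTSeq assigned to no counted feature. Whether reads in introns are among them depends on settings not given in the sources used here. This share was 7.80% (95% Clopper-Pearson interval 7.79% to 7.81%) in the unscratched and 8.02% (8.02% to 8.03%) in the scratched parental library. In the 4 mutant libraries it lay between 4.98% and 6.41%.

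The mutant lines carry knockouts of LINGO family receptors, leucine-rich repeat transmembrane proteins best known from neurons, and of TROY, a tumour necrosis factor receptor family member encoded by Tnfrsf19. Of the 4 targeted genes, Lingo1 (ENSMUSG00000049556, chromosome 9, 56618475 to 56796468, GRCm38) was the 1 with a clear transcript level. Lingo1 stood at 27.6 CPM in the unscratched and 24.5 CPM (95% Poisson interval 22.7 to 26.3) in the scratched parental library. It was higher in the Lingo1 mutant, at 57.0 CPM, which is 2.33-fold (2.13 to 2.55), in the Lingo2 mutant at 2.12-fold and in the Lingo3 mutant at 2.10-fold. In the TROY mutant the ratio was 1.42 (1.29 to 1.56), short of the size rule. A knockout need not lower a transcript, and the sequence of the gene was not examined here. The level of Lingo1 in its own mutant therefore neither bears out nor contradicts the label. Lingo2 (ENSMUSG00000045083, chromosome 4, 35706647 to 36951747) had 0 counts in all 6 libraries. Lingo3 (ENSMUSG00000051067, chromosome 10, 80832801 to 80844039) had 1 count in total, in the Lingo2 mutant. Tnfrsf19 (ENSMUSG00000060548, chromosome 14, 60963875 to 61046490) had 13 counts in total and between 0 and 4 in any library. The knockouts of Lingo2, Lingo3 and TROY therefore could not be checked at the transcript level, and no transcript of Lingo2 was detectable at this depth in the parental line. The fourth family member, Lingo4, had between 17 and 40 counts.

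The series title names epithelial wound healing, and the first comparison asks which transcripts differed 24 hours after the scratch in the parental line. Only 10 of the 12078 tested genes passed the size rule, 8 higher and 2 lower. Von Willebrand factor, Vwf (chromosome 6, 125546774 to 125686679), a clotting glycoprotein of endothelial cells, stood at 0.558 CPM without and 5.56 CPM with the scratch, 9.95-fold higher (5.95 to 17.8). Nrg1, a ligand of the ERBB receptors, went from 2.76 to 5.69 CPM, 2.06-fold higher (1.57 to 2.73). Dysf, dysferlin, a protein of membrane repair, was 3.77-fold higher (1.85 to 8.45). Map1b, a microtubule-associated protein, was 2.69-fold higher (1.87 to 3.94). Ltbp2, a matrix protein of the latent TGF-beta binding family, had 2 counts without and 20 with the scratch, a ratio of 9.42 (2.29 to 83.1). Boc, a cell surface receptor of the hedgehog pathway, was 2.65-fold lower (1.59 to 4.57), and Tnfrsf18, a tumour necrosis factor receptor family member, was 2.37-fold lower (1.52 to 3.78).

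The other 3 genes higher after the scratch were the pseudogenes Gm12912, Gm13456 and Rpl31-ps8, which fall outside the naming rule and are named because so few genes passed. Gm12912 had 2 counts without and 211 with the scratch, a ratio of 99.4 (27.2 to 826). Gm13456 was 3.26-fold higher (2.54 to 4.21) and Rpl31-ps8 2.53-fold higher (1.64 to 4.03). The scratched parental library held 102 genes, 71 of them pseudogenes, with at least 10 counts and at least 4 times the level in every other library. Gm12912 and Vwf were among the 102, which took 2469 counts. Without these 102 genes, a choice made after seeing the data, 8 genes passed. The 8 still included the pseudogenes Gm13456 and Rpl31-ps8, which fell short of 4 times the level in the unscratched library. Leaving out the 102 therefore need not leave out every transcript of that kind.

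No gene list had more than 1 gene past the rule with the scratch. None of the 24 measured immediate early and ERK target genes, among them Fos, Egr1 and Dusp1, passed the rule, and their median log2 fold was -0.03 (28.8th percentile of matched random lists). None of the 18 measured integrins, laminins and migration genes passed, with a median of -0.14 (0.16th percentile). None of the 20 S phase genes passed, with a median of -0.09. The 25 measured cholesterol and fatty acid synthesis genes had a median of 0.12 (100th percentile), 23 of them above 0 and none past the rule, with Hmgcs1, the enzyme that makes HMG-CoA, at 1.22-fold (1.17 to 1.27). Other lists outside the central 95% of random lists included the 3 measured endothelial markers, Vwf among them, with a median of 0.44 (99.77th percentile), the 5 airway genes with -0.35 (0.54th), the 11 alveolar type II cell genes with -0.17 (0.185th), the 7 mitochondrially encoded genes with 0.15 (100th) and the 29 axon guidance genes with -0.13 (0th). Of the 36 lists, 6 lay above and 8 below the central 95% of their random lists, where 0.9 would be expected each way by chance. With the mean of a list in place of the median, 8 lay above and 1 below. The culture-to-culture difference that a scratch would have to exceed was not measured.

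Every mutant library differed from the parental libraries in more genes than the parental libraries did from each other. The counts were 437 genes for the Lingo1 mutant, 423 for Lingo2, 868 for Lingo3 and 270 for TROY against the scratched parental library, and 383, 356, 827 and 272 against the unscratched one, a control added after seeing the data. Between mutants, the Lingo1 and Lingo2 libraries differed in 2 genes (the ribosomal RNA gene n-R5-8s1 and CT010467.1, the latter outside the naming rule), Lingo1 and TROY in 26, and Lingo2 and TROY in 44. The Lingo3 library differed from Lingo2 in 195 genes, from Lingo1 in 199 and from TROY in 315. Genotype, line and culture cannot be separated with 1 library per line, and no replicate was available to give the difference between cultures of 1 line. In the simulated lines without any effect, a mean of 1.4 genes per mutant passed the rule at a noise of 0.1, and 218 at 0.2.

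**Figure D1:**
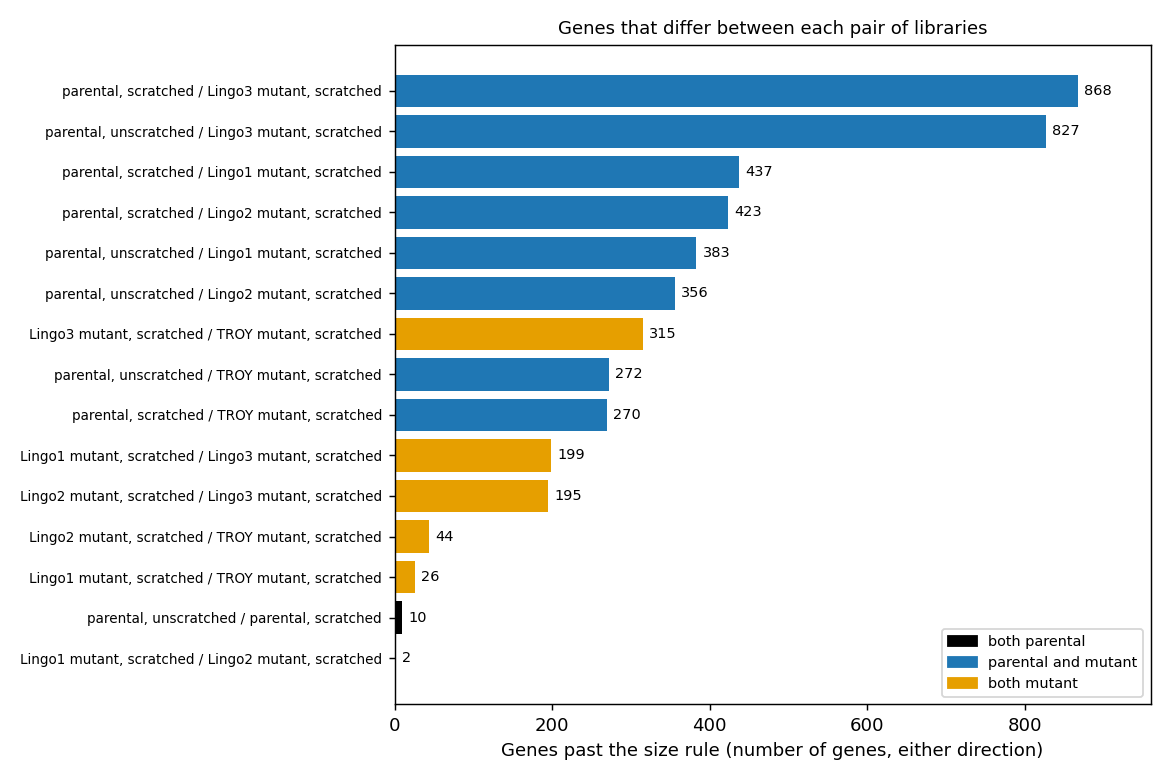
Number of genes past the size rule (horizontal axis, either direction, of 12078 tested) for each of the 15 pairs of the 6 libraries, with pairs of parental libraries in black, parental with mutant in blue and pairs of mutants in orange. The 8 parental-mutant pairs lie between 270 and 868 genes, against 10 for the parental pair and between 2 and 315 for the 6 pairs of mutants.

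The Lingo1 mutant was compared with the scratched parental line to ask which transcripts differ in the wounded monolayer of the Lingo1 knockout line. Fosb, Fos, Krt14, Sftpb and Sftpc were higher, and Neat1, Gpm6a and Twist1 were lower. Of 437 genes past the rule, 235 were higher and 202 lower. The transcription factor Gata5 (chromosome 2, 180325133 to 180334699) rose from 0.263 to 5.63 CPM, 21.4-fold (10.6 to 50.5). Cdh4, which encodes R-cadherin (chromosome 2, 179442431 to 179899373), had 0 counts in the scratched parental and 85 in the Lingo1 mutant library, at least 31.1-fold higher. Biglycan, Bgn, a small matrix proteoglycan, was 19.8-fold higher (12.99 to 31.5), phospholipase C beta Plcb1 9.82-fold (7.67 to 12.7) and Sez6l 15.0-fold (7.33 to 35.5). The acute phase gene Orm3 was 8.07-fold higher (6.37 to 10.3) and the mast cell protease gene Mcpt1 5.01-fold (4.68 to 5.36). Pdgfrb, a platelet-derived growth factor receptor, had 1 count in the scratched parental library and 52 in the mutant, a ratio of 57.1 (9.81 to 2298). Against the unscratched parental library, Pdgfrb did not pass the rule in every mutant. Among the lower genes, Gpm6a (chromosome 8, 54954843 to 55060871), a membrane glycoprotein known from neurons, fell from 36.0 to 4.26 CPM, 8.45-fold (6.98 to 10.3). Twist1, a mesenchymal transcription factor, was 12.6-fold lower (5.13 to 39.9), and Neat1, the long non-coding RNA of paraspeckles, 4.48-fold (4.32 to 4.65).

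Of the 24 immediate early and ERK target genes measured in the Lingo1 mutant, 9 were higher and none lower, with a median log2 fold of 0.59. Fosb was 9.68-fold higher (6.49 to 15.0), Egr2 5.33-fold (4.35 to 6.57), Atf3 4.48-fold (3.95 to 5.09) and Fos 4.33-fold (4.09 to 4.59). Of 11 measured genes of EGF receptor ligands and receptors, Ereg at 2.90-fold, Areg at 2.27-fold and Hbegf at 2.21-fold were higher, while the receptor Egfr was 2.07-fold lower (1.73 to 2.48). Of 18 measured integrins, laminins and migration genes, 3 were higher, among them Lamb3 at 3.46-fold and S100a4 at 2.78-fold, none was lower and the other 15 did not pass. The airway list had 5 measured members, of which 4 were higher: Trp63, a basal cell transcription factor, at 4.69-fold (3.04 to 7.49), Krt14 at 4.03-fold, the ciliated cell gene Tppp3 at 3.29-fold and Krt13 at 2.58-fold. Of 11 measured alveolar type II cell genes, Sftpb at 4.60-fold, Cd74 at 3.59-fold, Cebpa at 2.65-fold and Sftpc at 2.22-fold were higher and Cxcl15 was 4.07-fold lower (2.30 to 7.67). The cell cycle inhibitor Cdkn1a was 4.24-fold higher (3.52 to 5.14) and the only 1 of 15 measured p53 target genes past the rule. With total counts as the scaling, fewer of the genes past the rule were higher than lower (198 and 238), as with no expression filter (300 and 483), so the balance of directions rests on these settings.

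The same question was asked for the Lingo2 knockout line, and the Lingo2 mutant library was close to that of the Lingo1 mutant. In the Lingo2 mutant 256 genes were higher and 167 lower, against 207 and 200 with total counts and 351 and 404 with no expression filter, so the balance of directions rests on these settings. Gata5 was 26.4-fold higher (13.1 to 61.9), Cdh4 at least 24.0-fold, Bgn 16.6-fold (10.9 to 26.5), Orm3 9.37-fold (7.42 to 11.99) and Sprr2a3, a gene of the cornified envelope in a cluster of similar copies, 8.05-fold (6.49 to 10.1). Plcb1 was 8.14-fold higher (6.35 to 10.6) and Gkn2, a gastrokine of mucosal epithelia, 7.45-fold (5.31 to 10.7). Pdgfrb and the retinol receptor Stra6, each with 1 count in the scratched parental library, had ratios of 39.8 (6.72 to 1615) and 29.1 (4.79 to 1190). Gpm6a was 15.0-fold lower (11.7 to 19.4), Twist1 10.7-fold (4.67 to 30.1), the collagen gene Col11a1 8.65-fold (4.87 to 16.7), Syne4 5.42-fold (2.92 to 10.99), Tnfrsf4 4.65-fold (2.59 to 8.93), Dnah11 3.80-fold (3.15 to 4.60), Tnfrsf25 3.75-fold (3.04 to 4.65) and Neat1 3.40-fold (3.29 to 3.52).

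Of the 24 immediate early and ERK target genes, 7 were higher in the Lingo2 mutant, led by Fosb at 8.89-fold, Atf3 at 4.56-fold, Egr2 at 4.20-fold and Fos at 4.08-fold, and none was lower. In the Lingo2 mutant, 4 of 5 airway genes were higher, with Krt14 at 4.13-fold (3.89 to 4.39) and Trp63 at 4.06-fold (2.61 to 6.51). Of 11 alveolar type II cell genes 4 were higher, with Sftpb at 4.06-fold and Sftpc at 2.29-fold, and Cxcl15 was 2.39-fold lower. Of 11 EGF receptor ligands and receptors, Areg at 2.67-fold, Ereg at 2.58-fold and Hbegf at 2.07-fold were higher and Egfr was 2.08-fold lower (1.74 to 2.48). Of 18 integrins, laminins and migration genes, S100a4 at 3.20-fold, Lamb3 at 2.76-fold and Itga6 at 2.08-fold were higher. Of the 27 measured interferon response genes, Usp18 alone passed, 2.20-fold higher (1.54 to 3.17), with a list median of 0.40. Of 19 YAP/TAZ target genes Nt5e alone passed, 2.12-fold higher (1.89 to 2.39), and of 17 epithelial junction genes Epcam alone, 2.11-fold higher (1.68 to 2.65). None of the 25 cholesterol and fatty acid synthesis genes passed, although all 25 had folds above 1, with a median log2 fold of 0.56 and Scd1 at 1.80-fold (1.75 to 1.84).

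The Lingo3 mutant, compared with the scratched parental line for the same question, had the most genes past the rule, 559 higher and 309 lower. Biglycan, Bgn (chromosome X, 73483602 to 73495933), rose from 0.756 to 98.3 CPM, 130-fold (86.5 to 205). Col1a1 was 8.88-fold higher (8.40 to 9.40), at 398 CPM, the alkaline phosphatase gene Alpl 45.8-fold (23.0 to 107), Apol8 51.3-fold (21.7 to 159) and Dysf 32.7-fold (23.9 to 46.0). Sfrp1, a secreted Wnt antagonist, had 3 parental counts and 263 in the mutant, a ratio of 87.5 (29.6 to 427). The ratio was 53.2 (17.9 to 261) for the calcium channel subunit Cacng4, 136 (23.9 to 5399) for Stra6 and 347 (61.9 to 13754) for Pdgfrb, whose scratched parental counts were 3, 1 and 1. Cdh4 was at least 61.2-fold higher and Gata5 44.8-fold (22.5 to 105). Tenascin C, Tnc (chromosome 4, 63959785 to 64047015), fell from 58.0 to 6.30 CPM, 9.21-fold (7.93 to 10.7), and the basement membrane collagen gene Col4a6 (chromosome X, 141165403 to 141474076) from 137 to 17.5 CPM, 7.86-fold (7.18 to 8.62). Gpm6a was 15.7-fold lower (12.3 to 20.3), the amino acid transporter gene Slc7a3 10.3-fold (6.34 to 17.8), the proprotein convertase Pcsk5 6.99-fold (6.07 to 8.09) and Neat1 5.40-fold (5.19 to 5.61). The ribosomal RNA gene n-R5-8s1, which has near-identical copies, was 7.99-fold lower (6.38 to 10.1).

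Of the 24 immediate early and ERK target genes, 10 were higher in the Lingo3 mutant and none lower, with Fosb at 11.2-fold, Dusp4 at 6.20-fold (5.25 to 7.35), Egr2 at 5.75-fold and Atf3 at 5.10-fold. Of 25 cholesterol and fatty acid synthesis genes, 6 were higher and all had folds above 1 (median log2 fold 0.88), with Elovl6 at 2.62-fold (2.46 to 2.78), Scd1 at 2.57-fold and Hmgcs1 at 2.32-fold. Of 5 airway genes 4 were higher, with Trp63 at 15.8-fold (10.6 to 24.4) and Tppp3 at 5.04-fold. Of 11 alveolar type II cell genes 5 were higher, among them Cd74 at 6.10-fold (4.01 to 9.63), Sftpb at 4.61-fold and Sftpc at 4.47-fold, and Cxcl15 was 3.73-fold lower. Of 9 measured Notch pathway genes 3 were higher, with Notch1 at 15.6-fold (9.68 to 26.7) and Notch3 at 8.45-fold (4.93 to 15.5). Of 9 measured Wnt target genes 3 were higher, Lgr4 at 5.62-fold (4.56 to 6.98), Lgr5 at 4.63-fold (3.21 to 6.83) and Tcf7 at 2.42-fold. Of 5 measured fibroblast markers 3 were higher, with Pdgfra at 3.91-fold (2.87 to 5.42) beside Col1a1 and Pdgfrb. Of 18 mesenchymal and matrix genes, 3 were higher, among them Col5a1 at 6.35-fold and Snai1 at 2.18-fold, and Twist1 was 8.64-fold lower, with Tnc. Of 27 interferon response genes 3 were higher, Usp18 at 3.28-fold, Oas1a at 3.21-fold and Irf7 at 2.08-fold.

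The TROY mutant, compared in the same way, had the fewest genes past the rule among the mutants, 128 higher and 142 lower. This balance turned with a mean of at least 5 CPM (79 and 39), and with protein-coding genes only (123 and 84) or the unscratched library as control (150 and 122), both chosen after seeing the data. Fosb, Egr2, Atf3 and Gata5 were higher, while Sftpc was not past the rule. Gata5 was 19.2-fold higher (9.51 to 45.3), Cdh4 at least 16.5-fold, Fosb (chromosome 7, 19302696 to 19310051) 12.5-fold (8.47 to 19.3), Bgn 6.99-fold (4.50 to 11.3), Plcb1 6.72-fold (5.23 to 8.75) and Gkn2 5.91-fold (4.19 to 8.53). Sprr2a3 was 4.80-fold higher (3.84 to 6.05), Egr2 4.59-fold (3.74 to 5.68), Atf3 4.57-fold (4.04 to 5.19) and Atp6v0a4, a subunit of the proton pump, 4.44-fold (3.92 to 5.04). Gpm6a was 8.08-fold lower (6.75 to 9.74), the metalloprotease Adam8 5.21-fold (2.97 to 9.74), the chemokine Cxcl15 5.10-fold (2.79 to 10.1), Col11a1 4.60-fold (2.99 to 7.33), the monocarboxylate transporter gene Slc16a4 4.47-fold (2.77 to 7.56), Tstd1 4.19-fold (2.78 to 6.52), Neat1 4.17-fold (4.02 to 4.32) and Mss51 3.66-fold (2.86 to 4.74).

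Of the 24 immediate early and ERK target genes, 8 were higher in the TROY mutant, with Fos at 3.91-fold (3.69 to 4.14) and the ERK phosphatase gene Dusp4 at 3.06-fold (2.56 to 3.67), and none was lower. Of 25 cholesterol and fatty acid synthesis genes, Elovl6 at 2.16-fold (2.02 to 2.30) and Scd1 at 2.12-fold (2.07 to 2.17) were higher, and all 25 had folds above 1 (median log2 fold 0.66). Of 5 airway genes, Trp63 at 3.31-fold, Krt14 at 2.93-fold and Krt13 at 2.40-fold were higher. Of 4 measured trefoil factor and mucin genes, Muc5ac at 3.58-fold (2.62 to 4.97) and Muc5b at 2.89-fold (2.71 to 3.09) were higher. Of 18 integrins, laminins and migration genes, Hmga2 at 3.30-fold (1.82 to 6.34) and Lamb3 at 2.40-fold were higher. Of 11 alveolar type II cell genes, Sftpb at 2.44-fold was higher and Cxcl15 lower, while Sftpc had a ratio of 1.08 (0.964 to 1.22). Of 14 measured matrix proteases and inhibitors, Mmp2 at 2.32-fold (1.75 to 3.09) and Adam8 were lower and none was higher. Egln3, an oxygen sensor, was the 1 of 24 measured hypoxia and glycolysis genes past the rule, 2.37-fold higher (1.85 to 3.06).

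The design also asks which transcripts differed in the same direction in all 4 mutants. There were 189, 88 higher and 101 lower, with 0 found in 20 simulations with counting error alone, at most 1 with added noise of 0.1 and at most 8 with 0.2. More were higher than lower with a mean of at least 5 CPM (58 and 31), at a fold of at least 4 (16 and 3), and with protein-coding genes only (87 and 57) or the unscratched library as control (100 and 80), both chosen after seeing the data, so the balance of directions rests on these settings. Against both parental libraries, a check added after seeing the data, 136 of the 189 passed. In pairs, the Lingo1 and Lingo2 lists shared 189 higher and 137 lower genes, and the Lingo3 and TROY lists shared 111 and 114. Simulated lines without any effect, set against a shared control, shared at most 1 higher and 0 lower genes per pair at a noise of 0.1, and at most 33 and 18 at 0.2. The higher genes included Fosb at between 8.89- and 12.5-fold, Gata5 at between 19.2- and 44.8-fold, Atf3 at between 4.48- and 5.10-fold, Fos at between 3.91- and 4.55-fold and Atp6v0a4 at between 4.27- and 7.64-fold. Sprr2a3 was between 4.80- and 14.4-fold higher and Gkn2 between 5.91- and 8.62-fold. The lower genes included Gpm6a at between 8.08- and 15.7-fold, Neat1 (chromosome 19, 5824708 to 5845478) at between 3.40- and 5.40-fold, the splicing-related gene Rsrp1 at between 2.67- and 4.18-fold and the death receptor Tnfrsf25 at between 3.04- and 6.47-fold. Spaca6, Mss51, Gabre, the long non-coding Snhg20 and Acrbp were lower in all 4 as well, the weakest being Spaca6 in the TROY mutant at 2.67-fold (2.41 to 2.96). Vwf was between 4.58- and 14.3-fold lower, but its mutant levels of between 0.389 and 1.21 CPM stood near the 0.558 CPM of the unscratched parental library, and the pseudogenes Gm12912 and Gm13456, higher after the scratch, are also among the 101. Of the 88 higher genes 87 were protein coding, and of the 101 lower genes 57 were protein coding and 39 long non-coding, against 383 long non-coding genes among the 12078 tested. The no-feature share was lower in every mutant than in both parental libraries, as given above.

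**Figure D2:**
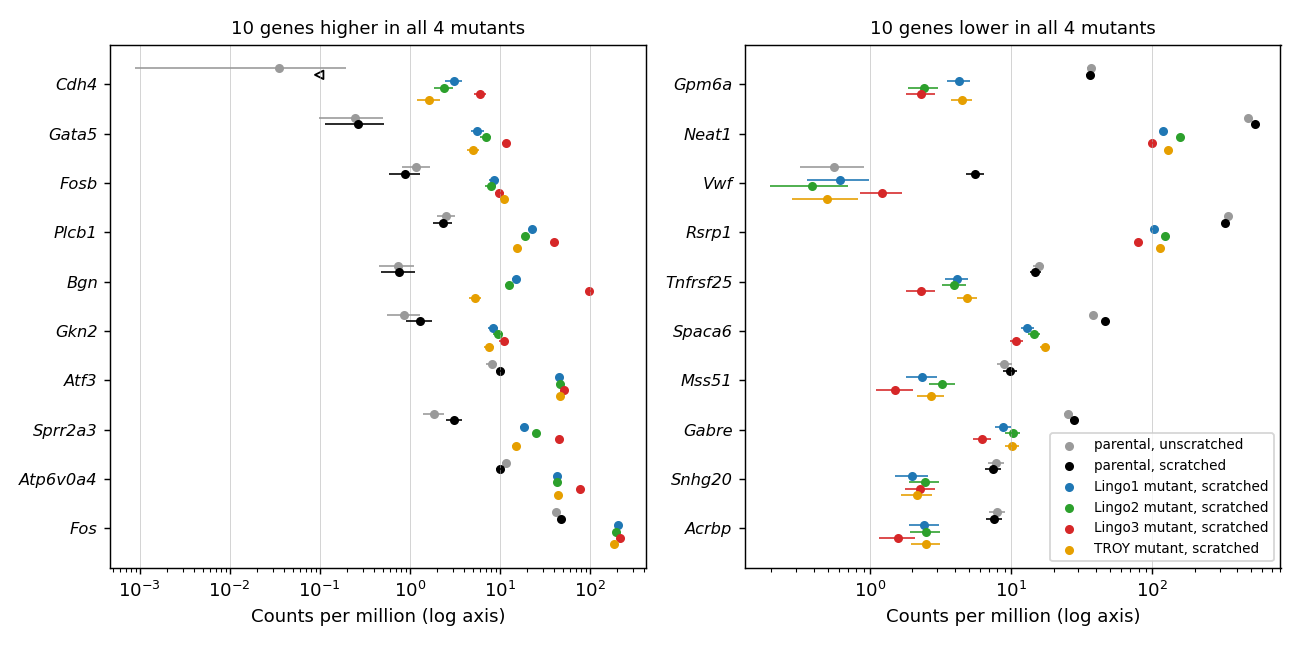
Level in CPM (horizontal log axis) in each of the 6 libraries for 10 genes higher and 10 genes lower in all 4 mutants, with 95% Poisson intervals and an open arrow at the 3-count floor where a library had 0 counts. Fos stands at 42.4 and 48.0 in the parental libraries and between 188 and 218 in the mutants, Neat1 at 480 and 537 against between 99.5 and 158, and Vwf is high in the scratched parental library alone.

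Correlation across genes (genes are not independent replicates) of the log2 folds of 2 mutants lay between 0.750 and 0.894 against the shared parental library. With 1 mutant set against the scratched and the other against the unscratched parental library, so that no library was shared, it lay between 0.662 and 0.815 for the 6 pairs. Simulated lines without any effect gave means of 0.49, 0.50 and 0.50 at a noise of 0, 0.1 and 0.2 when the control was shared. That value follows from sharing a control and not from the noise. The case without a shared library was not simulated.

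Several fixed lists moved the same way in the 4 mutants. Immediate early and ERK target genes had median log2 folds of between 0.50 and 0.78 with between 7 and 10 of 24 genes higher, and Dusp1, an ERK and stress kinase phosphatase, was between 2.28- and 2.59-fold higher. Cholesterol and fatty acid synthesis genes had medians of between 0.56 and 0.88, integrins, laminins and migration genes of between 0.51 and 0.80, and airway genes of between 1.26 and 2.23. Muc5ac and Muc5b, the gel-forming mucins, were higher in every mutant, between 2.67- and 3.82-fold and between 2.03- and 3.54-fold. The complement gene C3 was between 2.85- and 10.1-fold higher and Cdkn1a between 3.27- and 4.43-fold. Lgr4, a receptor of R-spondins, was between 2.16- and 5.62-fold higher, and the receptor tyrosine kinase Mst1r between 2.71- and 3.76-fold. Fgf7, a growth factor for epithelia, was between 2.60- and 4.25-fold lower. These folds are against the scratched parental library, and Muc5b and Fgf7 did not pass the rule in every mutant against the unscratched one. The 20 S phase genes had medians of between -0.11 and -0.07 (0.22th to 2.17th percentile), with none past the rule in any mutant. The 28 cytosolic ribosomal protein genes had medians of between -0.17 and 0.05 (0th to 6.065th percentile), also with none past it. The LINGO receptor complex list had 5 measured members, with Rtn4, which encodes the Nogo ligands, at between 1.11- and 1.23-fold, short of the rule in each mutant. Of the 36 lists, between 18 and 23 per mutant lay above the central 95% of their random lists, so that a high percentile alone sets few lists apart, and the correlated libraries do not make 4 independent tests.

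**Figure D3:**
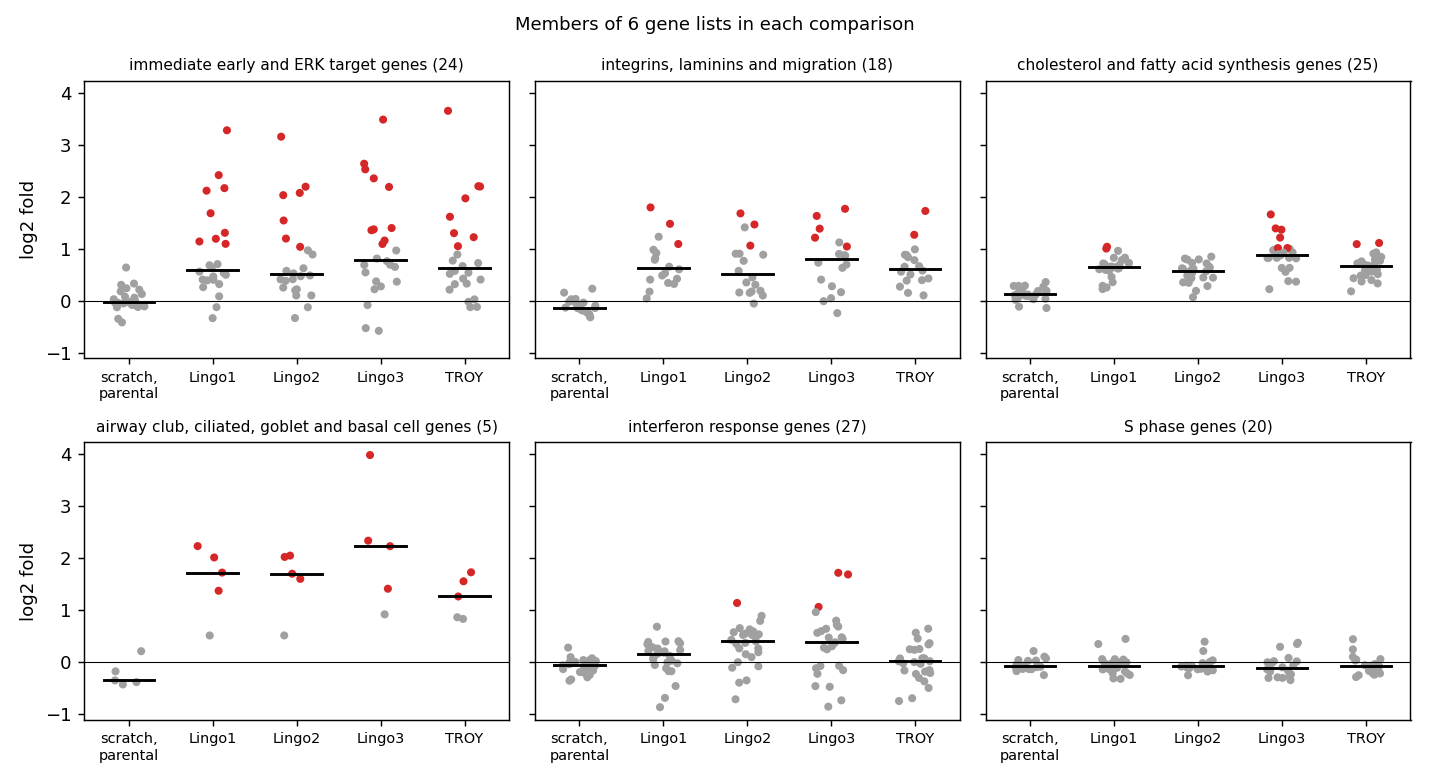
Log2 fold (vertical axis) of each measured member of 6 gene lists in the scratch comparison of the parental line and in each mutant against the scratched parental line, with red for genes past the size rule and higher, grey for the others, and a black bar at the median. The immediate early genes have a median of -0.03 in the scratch comparison and of between 0.50 and 0.78 in the mutants, while the S phase genes have none past the rule in any of the 5 comparisons.

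When each scratched library was set against the other 4, the Lingo1 and the Lingo2 mutant stood apart for 0 genes, the TROY mutant for 4 and the Lingo3 mutant for 122, of which 105 were higher and 17 lower. Those of the Lingo3 mutant included Bgn, Alpl, Apol8, Cacng4, Dysf and Dapk1 among the higher, with the death-associated kinase Dapk1 at 14.1 CPM against between 0.565 and 1.88 CPM in the other scratched libraries. Tnc, Col4a6, n-R5-8s1, Opcml, Mcpt2 and Pcsk5 were among the lower, with Opcml, a neural adhesion molecule, at 3.71 CPM against between 10.5 and 14.9 CPM. The TROY mutant stood apart for Steap4, a metalloreductase (chromosome 5, 7960457 to 7982213), at 0.698 CPM against 2.93 CPM in the scratched parental library, 4.19-fold lower (2.58 to 7.10), and for Dapk1 (chromosome 13, 60601947 to 60763191), 3.03-fold lower (1.72 to 5.58). The other 2, named because they are so few, were the pseudogene Rpl31-ps8, lower, and the predicted gene Gm23935, higher. The scratched parental library stood apart for 189 genes, which by construction are the genes past the rule in all 4 mutants. The closest library in the set caps each of these numbers, and the Lingo1 and Lingo2 libraries differed from each other in 2 genes. The unscratched parental library, which differed from the scratched one in 10 genes, was not in the set.

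The 8 genes higher after the scratch in the parental line were also followed in the mutants, to ask whether scratched mutant cells sat at the scratched or the unscratched parental level. Their median log2 fold was 1.81 with the scratch. In the Lingo1, Lingo2, Lingo3 and TROY mutants the medians were -0.50, -0.48, -0.25 and -1.58 against the scratched parental library. Against the unscratched one they were 0.75, 1.02, 1.12 and 0.84 over 7 of the genes, without Gm12912, which had too few counts there for a fold, and 0.69, 0.71, 1.08 and 0.55 with it counted as unchanged, a choice made after seeing the data. In the 9 of 20 simulations (noise of 0.1, no mutant effect) that called any gene, where selection alone pulls these values apart, the medians were -0.50 and 0.82, for genes with a smaller median of 1.31 with the scratch. Over the 3 genes with a scratch fold of at least 4, the Lingo1 and Lingo2 medians against the scratched parental library were -3.18 and -3.84. The Lingo3 and TROY medians were also lower than over all 8, and these few genes do not settle the question. Vwf and Gm12912 were among the 102 genes that stood out in the scratched parental library. RNA from another organism may be their source, so low values against that library need not mean a lost response to the scratch. Dysf was 32.7-fold higher in the Lingo3 mutant than in the scratched parental line and Ltbp2 16.2-fold, while Nrg1 did not pass the rule in any mutant. Boc was higher in the Lingo2 and Lingo3 mutants than in the scratched parental library, and Tnfrsf18 did not pass the rule in any mutant.

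The authors' deposited table gave log2 ratios that correlated across 11819 matched genes with those computed here at between 0.99988 and 0.99999. In it, 84 genes were at least 1 log2 unit higher and 50 lower with the scratch. The numbers at least 1 log2 unit higher and lower were 391 and 444 for the Lingo1 mutant, 450 and 378 for Lingo2, 793 and 589 for Lingo3, and 260 and 363 for TROY. These counts have no condition on counting error and another filter on low genes, and they are larger than the counts above.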

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

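The tests weighed here were chosen only after the results they bear on had been seen.

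The 102 genes that stood out in the scratched parental library, each at least 4 times its level in every other library, took 0.00843% (95% Clopper-Pearson interval 0.00810% to 0.00876%) of its counts, while 0, 0, 1, 82 and 2 genes stood out in the unscratched parental, Lingo1, Lingo2, Lingo3 and TROY libraries, none of the 82 a pseudogene. Mouse endothelial cells as the whole cause are argued against, because 71 of the 102 are pseudogenes. Of 10 endothelial markers 4 stood out (Vwf, Cdh5, Tie1 and Cldn5), and Kdr at 74 and Esam at 47 counts were also highest there, while Pecam1 had 8 and Emcn 0 counts. Pseudogenes made up 69.6% of the 102 genes against 13.97% of the 24684 genes with a count, so a trace of RNA from another organism, endothelial or not, may be the source. The reads themselves were not analysed here, and a response of the parental line to the scratch was not tested, since the 102 genes were chosen as low in every mutant.

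In all 4 mutants, 189 genes passed the rule in the same direction. Noise of the 1 parental library they share is argued against as the whole cause, because 136 of them passed against both parental libraries. Loss of unspliced or nuclear RNA from the mutant libraries was weighed next. In the scratched parental library, losing every other uniquely aligned read would raise protein-coding counts evenly by 1.15-fold. An even rise of this size is below the smallest fold of 2.01 among the 88 higher genes. This comparison cannot decide the question, because the 88 were chosen at 2-fold or more and the scaling removes a rise common to most genes. Reads that aligned to more than 1 place were also left out of it. For the 101 lower genes such loss cannot be told apart from regulation, because the direction would be the same under either account. The 343 long non-coding genes outside the pattern had a median log2 fold of -0.092 in the Lingo2 mutant (resampling interval -0.14 to -0.0065), with 192 of them below 0. In the other mutants it lay between -0.23 and -0.18, with between 209 and 222 below 0. The no-feature share was 7.80% and 8.02% in the parental libraries against between 4.98% and 6.41% in the mutants. These medians are smaller shifts than the at least 2-fold of the 101 genes, of which 57 were protein coding. An equal loss of that size for all such transcripts would fall short, while a loss that differs between transcripts was not tested. Derivation, passage or handling of the mutant lines is confounded with genotype, so it stays open, and against an effect of a shared receptor complex stands that the parental libraries held 0 counts of Lingo2 and Lingo3 and 0 and 1 of Tnfrsf19 (upper limits of between 0.121 and 0.183 CPM), which does not exclude it, since the proteins were not measured.

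The Lingo3 mutant stood apart for 122 genes. The Lingo1 and Lingo2 mutants stood apart for 0, but they differed from each other in 2 genes, which caps their numbers. Of the 122 genes, 6.56% (8 genes) lie on chromosome 4, against 6.425% of the tested genes. This share cannot decide whether extra copies of chromosome 4 are a cause. The size rule asked for at least 2-fold, while the median shift of that chromosome was 0.19 log2 units. Effects of such copies on genes of other chromosomes were not tested. Fibroblasts mixed into the culture are argued against, because just 1 of 4 abundant fibroblast transcripts, Dcn, reached 0.1 times the level of Col1a1 in this library. Col1a1 stood at 398 CPM and Dcn at 2997 CPM, and Dcn stood at 2532 CPM in the scratched parental library too. Col3a1, Col1a2 and Lum stood at 2.03, 0.0984 and 0.0328 CPM. The low level of Col3a1 was still a rise, in the direction that such cells would give. It had 62 counts here, 0 in both parental libraries and between 1 and 3 in the other mutants. The drift of 1 derived line stays open and was not tested. Against the knockout of Lingo3 stands that this gene had 0 counts in both parental libraries (upper limits of 0.129 and 0.121 CPM), which does not exclude it, since the protein was not measured.

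In 4 genes, mutants passed the size rule in opposite directions against the scratched parental library, and in each case the difference was not tested, because no replicate gives its error. Dapk1 had a log2 fold of 3.04 in the Lingo3 and of -1.60 in the TROY mutant. Itga9, an integrin subunit outside the naming rule, had 1.99 in the Lingo3 and -1.16 in the TROY mutant. Mcpt2, a mast cell protease gene with a close neighbour copy, had 1.05 in the Lingo1, 1.03 in the Lingo2 and -1.56 in the Lingo3 mutant. Pde1c, a phosphodiesterase gene outside the naming rule, had -1.31 in the Lingo1 and 1.35 in the Lingo3 mutant.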

How the results depend on the processing

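The alternatives that used the unscratched or both parental libraries, protein-coding genes only, no genes that stood out in the scratched parental library, or genes without a fold counted as unchanged were chosen after seeing the data, and the others were planned. No paired analysis was possible because the labels give no replicate numbers and each group has 1 library.

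The choice of scaling changed the counts little and the balance of directions more. DESeq2 size factors gave 11 genes for the scratch, 440, 414, 864 and 270 for the Lingo1, Lingo2, Lingo3 and TROY mutants and 189 in all 4. Total counts gave 10, 436, 407, 856 and 278, with the higher share of the Lingo1 list at 45.4% in place of 53.8% and that of the TROY list at 38.1% in place of 47.4%. The median of all tested genes then moved to between -0.06 and 0.02 log2 units. Of 548 values of named genes past the rule under these 2 scalings, 524 stayed past it and 24 did not, all in the same direction.

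The thresholds set the counts, by construction of the filters. For the scratch comparison there were 160 genes with no expression filter, 2 with a mean of at least 5 CPM, 119 at a fold of 1.5, 3 at a fold of 4 and 33 with no condition on the interval. In the same order without the last, there were 783, 207, 1415 and 69 for the Lingo1 mutant, 755, 185, 1386 and 54 for Lingo2, 1487, 461, 2332 and 205 for Lingo3, and 562, 118, 1098 and 36 for TROY. With no condition on the interval the mutants had 542, 528, 968 and 364. In all 4 mutants there were 89 genes at a mean of at least 5 CPM and 19 at a fold of 4. The Lingo3 mutant stood apart for 52 and 25 genes under these 2 settings, and the TROY mutant for 1 and 0. The balance of directions turned with some of these settings. The Lingo1 and Lingo2 lists had more lower than higher genes with no expression filter (300 higher and 483 lower, and 351 and 404). The TROY list had more higher than lower genes with a mean of at least 5 CPM (79 and 39), at a fold of 1.5 (575 and 523), with no condition on the interval (186 and 178), with protein-coding genes only (123 and 84) and with the unscratched parental library as control (150 and 122). With protein-coding genes only, 7, 353, 348, 757 and 207 genes passed in the 5 comparisons and 144 in all 4 mutants. With the unscratched parental library as control, 306, 279, 693 and 193 genes of the 4 mutant lists were past the rule again.

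A fold of at least 4 in the scratch comparison leaves 3 genes. Their median log2 fold then moved to -3.18 in the Lingo1 and -3.84 in the Lingo2 mutant against the scratched parental library. Against that library the Lingo3 and TROY medians fell as well. In the Lingo3 mutant against the unscratched parental library the median moved to 4.19. The value of 4.19 rests on Vwf and Ltbp2, because Gm12912 had too few counts for a fold there, and with Gm12912 counted as unchanged it is 1.12, as without this setting. With the mean in place of the median, the sign turned for 6 of the list medians that lay outside the central 95% of their random lists, and signs that turned among the other lists were not counted. The 6 were the mesenchymal and matrix genes with the scratch (0.047) and in the Lingo2 mutant (-0.00093), the TGF-beta and BMP pathway genes with the scratch (0.11), and the endothelial markers in the Lingo1 (-0.31), Lingo2 (-0.59) and TROY (-0.56) mutants, where Vwf is 1 of 3 measured members. Of the other list medians under an alternative, 448 stayed within the spread of random lists and 81 moved beyond it without such a turn. By the mean, 1 list lay below the central 95% of random lists with the scratch, in place of 8, and with random lists of protein-coding genes 1 did in the Lingo2 mutant, in place of 2. Lingo2, Lingo3 and Tnfrsf19 had too few counts for any comparison at this depth.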

Other observations

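Of the tests here, that of chromosome 4 along its length was chosen only after the shift of that chromosome had been seen, and the lists and the chromosome shifts were planned.

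Further genes of the fixed lists passed the rule in some mutants. Of 15 measured growth factor and insulin-like growth factor genes, Igfbp4 was 2.26-, 2.02- and 2.96-fold higher in the Lingo1, Lingo2 and Lingo3 mutants, and Igfbp5 was 2.97-, 2.26- and 2.19-fold higher in the Lingo1, Lingo2 and TROY mutants. Of the 18 TGF-beta and BMP pathway genes, Inhba, an activin subunit, was higher in the Lingo1, Lingo3 and TROY mutants at 2.18-, 2.77- and 2.02-fold, and Ltbp1 in the TROY mutant at 2.13-fold (1.83 to 2.49). The endothelial receptors Tek and Flt1 were expressed by the parental line, at 86.5 and 7.86 CPM in the scratched library, and Flt1 was higher in the Lingo1, Lingo2 and Lingo3 mutants at 2.23-, 2.21- and 4.57-fold. Whether any of these differs between mutants was not tested.

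In the Lingo3 mutant, the axon guidance genes Sema4a, Efnb1 and Sema3b, of 29 measured, were higher and Sema3a was 2.86-fold lower (2.75 to 2.98), and of 3 measured neuronal genes Tubb3 was 3.06-fold and Uchl1 2.17-fold higher. Of 18 measured NRF2 target genes Gsta4 and Pgd were higher, and of 5 measured members of the LINGO receptor complex list Rtn4rl2, a Nogo receptor homologue, was 3.83-fold higher (2.67 to 5.63) beside Lingo1. Xist, the long non-coding RNA of X inactivation, stood at 521 and 537 CPM in the parental libraries and was 2.10-, 2.29- and 2.70-fold lower in the Lingo1, Lingo2 and Lingo3 mutants, and 1.41-fold lower (1.37 to 1.44), short of the rule, in TROY. Mcpt1 was 5.01-, 4.69- and 2.95-fold higher in the Lingo1, Lingo2 and TROY mutants and short of the rule in Lingo3 at 1.76-fold (1.63 to 1.90).

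The 776 tested genes of chromosome 4 had a median log2 fold 0.19 above that of all genes in the Lingo3 mutant, outside the range of -0.029 to 0.033 of 95% of random gene sets. The shift was 0.07 in the Lingo2 mutant and -0.10 for chromosome 14 in the Lingo3 mutant. Shifts outside the random range were common, so lying outside it does not single out a chromosome. Chromosome 2 lay above it in the Lingo1, Lingo2, Lingo3 and TROY mutants (0.040, 0.042, 0.072 and 0.058), and chromosome 5 below it in each. With the scratch in the parental line, chromosomes 7 (-0.036) and 15 (-0.031) lay below and X (0.038) above. A hypothesis is that part of the Lingo3 mutant cells may carry an additional chromosome 4. If so, the shift should run along the whole chromosome, with each block above 0.05, and all 13 successive blocks of about 60 genes had a positive median log2 fold, the lowest at 0.10 (0.1024) and the highest at 0.38. In the Lingo2 mutant the blocks lay between 0.019 and 0.15, all positive but not all above 0.05. DNA was not analysed here, so a coordinated change in expression without a change in copies was not excluded.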
